A study of Mus musculus with 4 samples.

How the data were processed

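The series holds RNA sequencing of 4 samples of sorted mouse periosteal macrophages, CX3CR1+ACE+ with vehicle or periostin and CX3CR1+CD74+ with vehicle or periostin, 1 library per group. Groups were taken from the sample labels, and every sample was assigned. Per the labels, total RNA was extracted after 24 h of treatment and libraries were made with a TruSeq kit. The submitters' processing notes name HISAT2 and the build GRCm38, without versions; the counting tool, its strand setting and the annotation release are not given in the sources used here.

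For each subset the authors deposited a table of genes with a signal per library, which proved to be read counts divided by 1 size factor per library. In each column 100% of values were whole multiples of 1 step within 0.001 read, so whole reads were recovered by division. The authors scaled the signal of all 4 libraries together, since the deposited mean equalled the mean over the 4 libraries for all 14398 genes in both tables. Levels could therefore be set across the 2 tables. The authors' deposited log2 fold changes equalled the log2 ratio of the 2 columns within 0.00500, with no pseudocount, and were not used for calls. At 2-fold those deposited log2 changes give 1385 genes higher and 1108 lower in ACE+ cells and 1705 and 1219 in CD74+ cells. The authors also deposited, for genes they took as higher in each subset, annotation terms with an enrichment p-value, a Benjamini adjusted p-value and a fold enrichment ratio. These enrichment sheets have the layout of a DAVID functional annotation chart, and the gene selection behind them is not given in the sources used here.

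The tables listed 17210 genes for ACE+ cells, 14720 for CD74+ cells and 17532 in either. A gene was listed only where both libraries of the table had at least 1 read. Reads of genes left out of a table were worked out from the deposited mean wherever the other table lists the gene, within 0.0001 read. Gene identifiers were matched to GENCODE mouse release M21 for coordinates, length and GC content, which covered 17384 genes, and 124 genes had no symbol. Of the deposited symbols, 19 had been turned into dates and were restored by gene identifier. No column of per-sample values was left unused.

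Deposited values were divided by the mean of the 4 column totals, 15573211, and multiplied by 1000000 to give scaled counts per 1000000 (CPM). The analysis plan had assumed counts or CPM, FPKM or TPM values, and this unit was chosen as the nearest to it when the files proved to hold scaled counts. Genes with at least 1 CPM in the higher library were compared, and the change was log2 of the levels after adding 1 CPM. With 1 library per group no comparison within a subset has residual degrees of freedom, so genes were counted there at a change of at least 2-fold, without a p-value. A fit of the periostin effect common to both subsets, added after seeing the data, took subset as a block and left 1 residual degree of freedom among the 4 libraries. It used quasi-likelihood tests in edgeR with TMM factors and Benjamini-Hochberg adjustment over the 13129 genes past the filter in both subsets, and treats any difference between the subsets' responses as error. Responses of the 2 subsets were compared by Spearman and Pearson correlation across genes and by counting genes whose log2 changes differed by at least 2, that is 4-fold. Folds of named genes carry exact 95% intervals from the conditional binomial distribution of the recovered reads. The number of calls that sampling of reads alone would give came from 20 simulated pairs of libraries with equal levels and counting noise only. The depth gave a median of 219, 282, 332 and 210 reads per listed gene in ACE+ vehicle, ACE+ periostin, CD74+ vehicle and CD74+ periostin. A count of 0 allows up to 3 reads, which is 0.188, 0.147, 0.179 and 0.269 CPM.

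There were 35 gene lists, fixed with the 2-fold rule, the naming rule and the first set of alternatives before the data were examined. Each list's median log2 change was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart at a percentile of at most 2.5 or at least 97.5, and lists with fewer than 5 measured members gave values only. The percentile describes these libraries and is no p-value across samples, and the expression-matched percentiles for the vehicle comparison were added after seeing the data. Lists of 22 chondrocyte markers and 4 Y-linked genes were added after seeing the data.

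Named genes were chosen by rule. In each periostin comparison and direction these were the 10 genes with the largest change among genes with a protein-coding symbol, predicted names left out, and at least 5 CPM in the higher library. For each list that stood apart, the 2 members with the largest change in its direction and the 1 with the largest in the other were named. For the difference of responses and the vehicle comparison, the 5 genes with the largest value in each direction were named. Ptprc, Cx3cr1, Ace, Cd74, Postn, Itgav, Itgb3 and Itgb5 were always named. A few genes that these rules name are not reported here.

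The alternatives fixed beforehand were pseudocounts of 0.1 and 5, rescaling by the median ratio or by TMM factors from edgeR, no filter or a minimum of 5 CPM, a 1.5-fold threshold, and random lists drawn without matching; 2000 random lists were drawn where the genes or values changed. Alternatives chosen after seeing the data were a binomial test on the recovered reads added to the 2-fold rule, removal of a running median over gene length in windows of 501 genes, random lists matched on length or on GC content in 10 bins beside expression in 5 bins, lists matched on expression in 5 bins alone, and genes left out of a table included. The binomial test at a Benjamini-Hochberg adjusted 0.05 called 44.2% of genes in ACE+ cells, 65.7% in CD74+ cells and 66.3% between the vehicle libraries. It compares libraries, not conditions, and was not used as the main rule.

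The gene rule was tested on simulated data of the same depth, with counting noise only and 100 genes changed by each size. Of genes changed 4-fold, 95% were recovered in ACE+ and 99% in CD74+ cells, and of genes changed 2.83-fold 79% and 88%, with 0 and 1 unchanged genes past the threshold. Among simulated lists of 20 genes, 100 of 100 shifted by 0.5 on the log2 scale stood apart and 3 of 100 unshifted lists did. No variation between cultures was simulated, so these figures do not give the error of the rules in the real data. Real log2 changes had a standard deviation of 0.39 in ACE+ and 0.65 in CD74+ cells, against 0.14 and 0.16 from sampling alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.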

Results

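Gene expression was measured by RNA sequencing in macrophages sorted from mouse periosteum, the membrane that covers bone. CX3CR1+ACE+ and CX3CR1+CD74+ cells came from male mice at postnatal day 28, were cultured with 10 ng/ml M-CSF, a macrophage growth factor, and received recombinant periostin at 500 ng/ml or PBS vehicle for 24 h. Periostin is a secreted matrix protein that binds integrins. The 4 groups, vehicle and periostin in each subset, held 1 library each, so no difference within a subset had a replicate spread or a test across samples behind it. Recovered reads came to 15471245 for ACE+ vehicle, 19798150 for ACE+ periostin, 16650349 for CD74+ vehicle and 11846312 for CD74+ periostin. In the same order, 1 read equalled 0.0627, 0.0491, 0.0598 and 0.0897 CPM. Levels are given as scaled counts per 1000000 (CPM), and each fold is a ratio of levels with its exact 95% counting interval. These intervals cover counting error only, not variation between cultures or animals. A gene counted as risen or fallen at a change of at least 2-fold with 1 CPM added to both levels, and a gene list when its median lay outside the central 95% of random lists matched on expression.

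Markers used for sorting were detected in all 4 libraries. Ptprc, which encodes CD45, had 618 and 560 CPM in ACE+ cells with vehicle and periostin, and 458 and 363 in CD74+ cells. Cx3cr1, the fractalkine receptor gene, had 16.9 and 21.7 in ACE+ cells and 18.2 and 14.5 in CD74+ cells. Ace, the angiotensin-converting enzyme gene, had 2.76 and 2.80 in ACE+ cells against 0.897 and 9.51 in CD74+ cells. Cd74, the MHC class II invariant chain gene, had 531 and 552 in ACE+ cells against 850 and 1222 in CD74+ cells. The gene for periostin itself, Postn, had 27.2 and 28.4 in ACE+ cells and 12.1 and 10.7 in CD74+ cells. Of the genes for integrin subunits that bind periostin, Itgav lay between 91.0 and 124, Itgb5 between 116 and 152, and Itgb3 between 541 and 1200 CPM.

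Periostin in CX3CR1+ACE+ macrophages was compared with vehicle to ask how this subset responds. Several cartilage and matrix genes were among those that rose most. Col2a1 (ENSMUSG00000022483, GRCm38 chromosome 15, 97975602 to 98004695), the main fibrillar collagen of cartilage, rose from 134 to 520 CPM, 3.88-fold (3.71 to 4.07). Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which encodes the joint lubricant lubricin, rose 5.39-fold (4.33 to 6.77). Loxl2 (ENSMUSG00000034205, chromosome 14, 69609068 to 69695834), a collagen-crosslinking oxidase, rose from 1.63 to 15.5 CPM, 9.48-fold (6.35 to 14.7). Aldh3a1 (ENSMUSG00000019102, chromosome 11, 61207537 to 61218421), an aldehyde dehydrogenase, fell from 9.91 to 0.834, 11.9-fold (7.19 to 20.9).

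The other 7 genes named by rank as higher in ACE+ cells also included matrix components. The cartilage collagens Col9a3 and Col11a1 rose 4.94-fold (3.94 to 6.27) and 3.97-fold (3.52 to 4.50). Mfap5, a protein of elastic microfibrils, rose 5.90-fold (4.05 to 8.89), and Ltbp4, which binds latent TGF-beta, rose 3.35-fold (2.60 to 4.36). Prg2, which encodes eosinophil major basic protein, rose from 2.38 to 17.1 CPM. Jchain, which joins immunoglobulin polymers, rose from 0.815 to 5.54, and the zinc finger gene Zfp521 from 1.57 to 6.67. In a list of 22 chondrocyte markers, written only after these genes had been seen, all 15 markers past the filter were higher with periostin and 10 rose at least 2-fold. Its median log2 change was 1.21, above all 10000 matched random lists. All 21 markers listed for ACE+ cells, the weakly expressed ones included, came to 311 CPM in sum with vehicle and 957 with periostin. Among genes named by rank as lower, Saa3, an acute-phase protein gene, fell 3.85-fold (2.92 to 5.15), and Itih3, a hyaluronan-binding protein gene, fell from 5.52 to 0.883. Gpr153 fell 3.53-fold, Mcc 4.60-fold, Crtam, an adhesion gene of cytotoxic lymphocytes, 3.66-fold, the elastin gene Eln 4.82-fold, Ehbp1 4.61-fold, Msrb2 3.36-fold and the calcium channel gene Cacna1d 3.56-fold.

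Gene lists for macrophages and inflammation shifted slightly upward in ACE+ cells, where the change was also correlated with GC content (Spearman 0.24 across genes). Macrophage identity genes rose as a list, with 15 of 22 members higher and a median log2 change of 0.15. Its member Aif1 rose from 2.76 to 7.26 CPM, Cx3cr1 stood at 21.7 against 16.9, and Lyve1, a marker of perivascular macrophages, fell from 15.1 to 6.62. MHC class II presentation genes had 12 of 16 members higher and a median of 0.18, with H2-Eb2 at 12.2 against 5.90 and the costimulatory receptor Cd40 at 12.3 against 9.03 CPM. H2-Oa, at 2.55 against 3.14, was its largest decrease, and 22.8% of its exon length overlaps other genes. Inflammatory cytokines and mediators had 14 of 18 members higher and a median of 0.19. Il18 rose from 0.565 to 2.75 and Lif from 6.15 to 14.7 CPM, while Saa3 fell in the same list. NF-kB feedback genes had 12 of 16 members higher and a median of 0.18, led by Relb at a 1.40-fold ratio (1.29 to 1.52) and Nfkbib at 1.28-fold (1.16 to 1.41), with Rel lower at 21.8 against 25.2. For Nfkbib, 16.4% of the exon length overlaps other genes. Osteoclast genes had 15 of 19 members higher and a median of 0.14. Tnfrsf11a, the RANK receptor gene, had a 1.34-fold ratio (1.14 to 1.58) and the myosin gene Myo1d stood at 82.7 against 59.8 CPM, whereas Itgb3 stood at 1012 against 1200. Matrix remodelling enzymes had 18 of 25 members higher and a median of 0.13, with Mmp3 at 26.3 against 15.4 and Adamts1 at 10.2 against 7.09 CPM. Mmp10 fell from 3.64 to 0.392.

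Markers of other blood cells moved with these lists in ACE+ cells. All 14 neutrophil markers were higher, with a median log2 change of 0.16. Mpo, the granule peroxidase gene, rose from 12.0 to 34.9 CPM, and 15.0% of its exon length overlaps other genes. Neutrophil elastase, Elane, had a ratio of 1.53 (1.26 to 1.85). Lymphocyte markers had 9 of 13 members higher and a median of 0.34. This came from weakly expressed genes of T and NK cells such as Cd3d and Nkg7, which had 1 read each with vehicle and 35 and 33 reads with periostin. The abundant B-cell gene Cd79a had 113 CPM against 156, and among members with at least 5 CPM the list median was -0.13. Ribosomal protein genes had 37 of 53 members higher and a median of 0.05, with Rpl37 at a 1.16-fold ratio (1.12 to 1.20) and Rpl15 lower at 223 against 252 CPM.

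Across all 14734 genes compared in ACE+ cells, 217 were at least 2-fold higher with periostin and 191 at least 2-fold lower, 1.47% and 1.30% of them. Sampling of reads alone gave 0.1 and 0 such genes on average over 20 simulated pairs of libraries, which held counting noise only. Percentiles of the 9 lists outside the random range were 99.0 for macrophage identity, 99.3 for MHC class II, 99.0 for inflammatory cytokines, 99.9 for NF-kB feedback, 99.4 for osteoclast genes, 99.5 for matrix remodelling, 97.6 for ribosomal proteins, 99.9 for neutrophil and 99.7 for lymphocyte markers. With a pseudocount of 5 the counts were 19 and 9, with 0.1 they were 644 and 574, and with random lists drawn without matching on expression, 5 lists stayed outside and the osteoclast, matrix remodelling, ribosomal and neutrophil lists came inside. A pseudocount of 5 brought macrophage identity inside at a percentile of 97.4, a minimum of 5 CPM brought inflammatory cytokines inside at 95.9, and matching on gene length, added after seeing the data, brought ribosomal proteins inside at 88.9, whereas the 5 expression bins used with it left them outside at 98.1. Matching on GC content, also added after seeing the data, brought ribosomal proteins and osteoclast genes inside at 94.0 and 96.7 and left the other 7 lists outside. Without a filter on low values, ribosomal proteins came inside at 97.3.

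**Figure D1:**
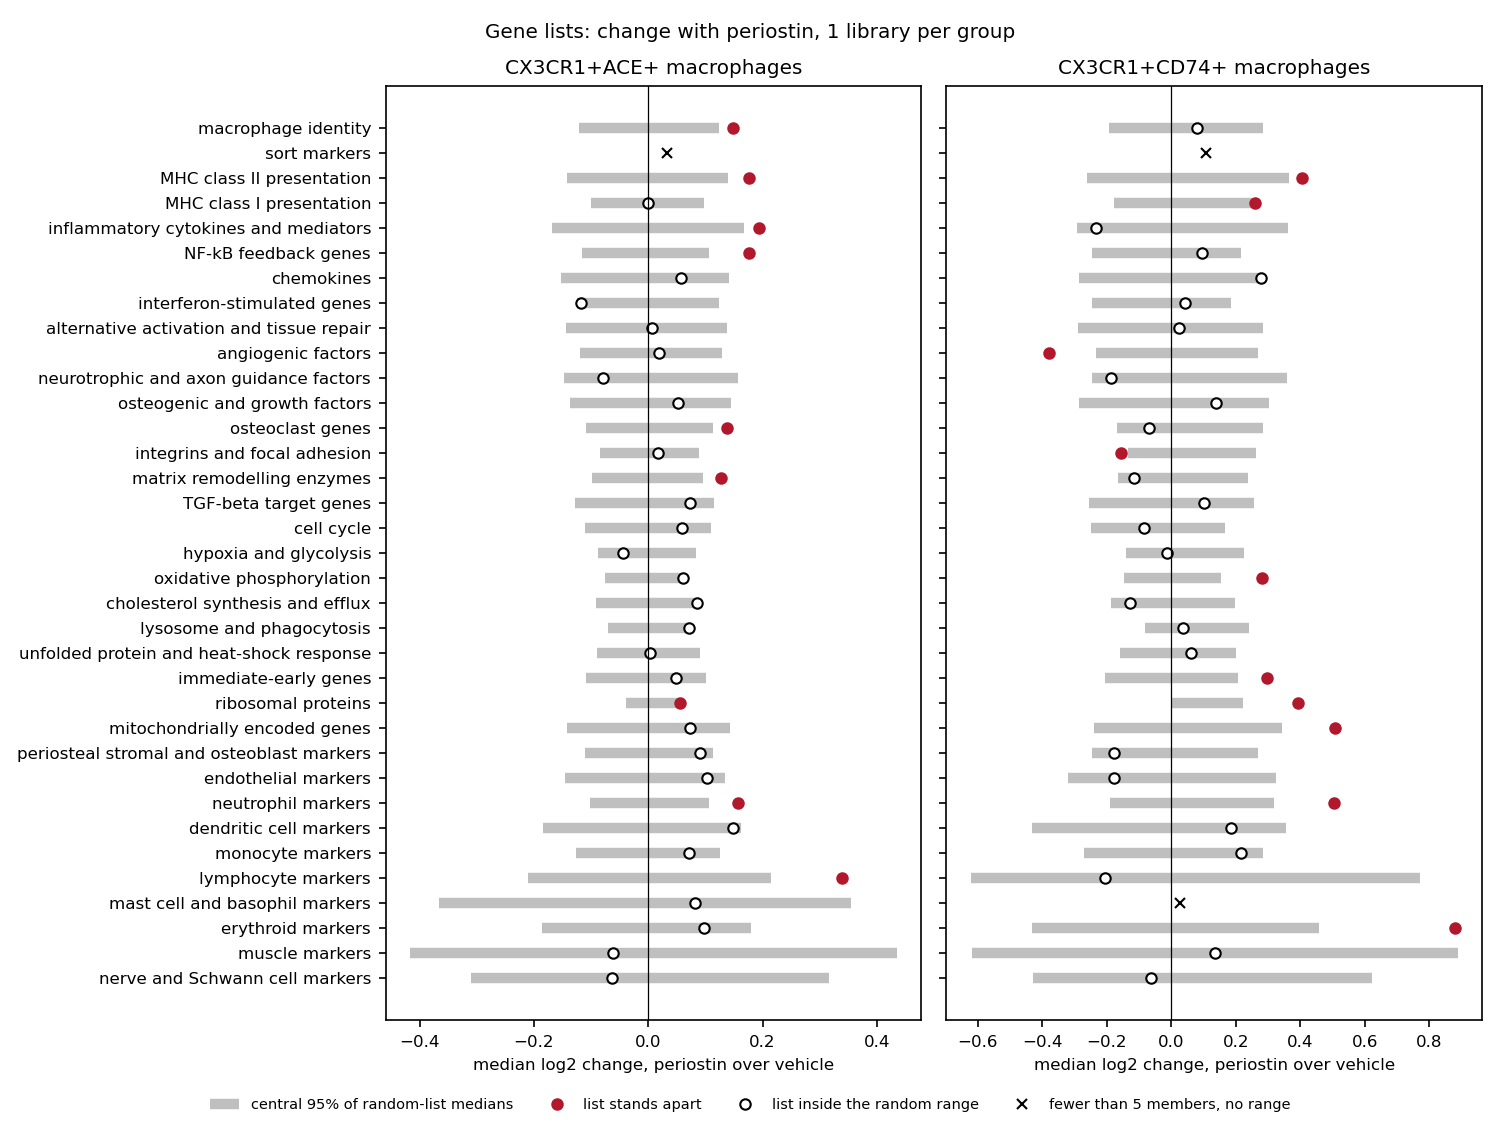
Median log2 change with periostin of each gene list (horizontal axis) in CX3CR1+ACE+ (left) and CX3CR1+CD74+ (right) macrophages, 1 library per group. Grey bars span the central 95% of 10000 random lists, filled points lie outside it and open points inside; 9 lists lie outside in ACE+ cells and 10 in CD74+ cells.

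Periostin in CX3CR1+CD74+ macrophages was compared with vehicle in the same way. The largest increase was in Retnla (ENSMUSG00000061100, GRCm38 chromosome 16, 48842551 to 48844461), a secreted protein gene known as a marker of alternatively activated macrophages, which rose from 0.359 to 36.6 CPM, 102-fold (46.5 to 280). Ace rose 10.6-fold (6.15 to 19.6) in these cells, and the immediate-early nuclear receptor gene Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) rose from 7.71 to 41.7, 5.41-fold (4.44 to 6.63). Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), the collagen of hypertrophic cartilage, fell from 169 to 6.01 CPM, 28.1-fold (22.03 to 36.3). Cd80 (ENSMUSG00000075122, chromosome 16, 38455561 to 38496335), a costimulatory ligand for T cells, fell from 16.6 to 1.44, 11.5-fold (6.98 to 20.5).

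Most of the other genes named by rank as higher in CD74+ cells started from a handful of reads, so their folds had wide intervals. Marco, a scavenger receptor gene, had 1 read with vehicle and 5.47 CPM with periostin, 91.5-fold (15.8 to 3673). Dkk1, a secreted antagonist of Wnt signalling, rose 30.8-fold (11.6 to 116) to 7.36, and C1qtnf3 rose 36.5-fold (12.0 to 181) to 6.55. Fibcd1 rose from 0.1196 to 5.92 and Zfp979 from 0.0598 to 5.47 CPM. Aldh1l1 rose from 0.179 to 6.73 and Dyx1c1 from 0.239 to 7.18, but 13.4% and 96.6% of their exon lengths overlap other genes, so reads of those genes were not excluded. Hist1h4h, a histone gene, rose from 1.08 to 14.7, and Serpina3i, a protease inhibitor gene, from 0.0598 to 5.83; both belong to families of closely similar genes. On the lower side, Ctse, which encodes the protease cathepsin E, fell 35.0-fold (13.5 to 129.6), from 12.6 to 0.359. Kcna3, a voltage-gated potassium channel gene, fell from 19.4 to 1.79, Reps2 from 20.7 to 1.26, Lmbrd2 from 16.5 to 1.26 and Nbas from 20.8 to 2.51 CPM. Palb2, a DNA repair gene, fell from 7.59 to 0.0897, Cwf19l2 from 11.6 to 1.17, and the small heat shock protein gene Cryab, with 17.0% of its exon length in other genes, from 8.49 to 0.628. Zbed6, a gene left out of the CD74+ table, had 405 reads in the vehicle library alone. Whether such a gap arose at a technical step, such as the authors' counting, is not known. The same limit applies to near-empty values such as 1 read for Palb2 and 4 reads for Ctse with periostin, and counting intervals do not cover it.

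Protein synthesis, respiration and antigen presentation genes shifted upward in CD74+ cells against lists matched on expression. Of the 6 lists that follow, only ribosomal proteins stayed outside the range when gene length was matched too. Their margin was narrow, at a median of 0.394 against an upper limit of 0.386. Ribosomal protein genes rose as a list, with 50 of 53 members higher and a median log2 change of 0.39, Rplp1 at a 1.91-fold ratio (1.86 to 1.96) and Rps24 at 1.87-fold (1.82 to 1.92). Rpl3 was the largest of the 3 decreases, at 412 against 421 CPM. Many ribosomal protein genes have processed pseudogenes that can share their reads. Oxidative phosphorylation genes had 29 of 36 members higher and a median of 0.28, with Uqcrb at 129 against 80.9 and Cox5b at 223 against 145 CPM, while Ndufs1 stood at 51.4 against 72.2. Genes encoded in mitochondrial DNA had 11 of 13 members higher and a median of 0.51, and mt-Nd3 and mt-Nd6 rose 2.66-fold (2.24 to 3.17) and 2.17-fold (1.98 to 2.38). The lower member named, mt-Atp8, stood at 4.66 against 5.62, with 21.1% of its length in other genes. MHC class II presentation genes had 12 of 16 members higher and a median of 0.41. The peptide-loading genes H2-DMb2 and H2-DMa rose from 2.33 to 6.82 and from 12.7 to 28.9 CPM, whereas Cd80 fell. MHC class I presentation genes had 15 of 18 members higher and a median of 0.26, with H2-Q7, one of a family of similar genes, at 56.6 against 32.6 and B2m at 3293 against 2138. The class I transactivator gene Nlrc5 stood at 31.3 against 53.4. Immediate-early genes had 17 of 23 members higher and a median of 0.30; besides Nr4a1, Nr4a2 rose from 7.06 to 15.6, and Egr2 stood at 5.83 against 10.2.

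Angiogenic factors shifted downward in CD74+ cells, and so did integrins by a call that 4 of 10 alternatives ended. Angiogenic factors had 18 of 24 members lower and a median log2 change of -0.38. Slit2, a guidance cue for axons and vessels, fell from 5.98 to 0.807 CPM, and Plau, the urokinase gene, had 47.5 against 89.9. Ang, with 18.2% of its exon length in other genes, rose from 1.32 to 3.95. Integrin and focal adhesion genes had 17 of 25 members lower and a median of -0.15, with Itga3 falling from 5.32 to 2.06 and Itga4 at 23.8 against 47.4, while Itga1 rose from 0.658 to 2.51. Markers of red and granulocytic blood cells shifted the other way, upward. Erythroid markers had 7 of 8 members higher and a median of 0.88, with Slc4a1, the red-cell anion exchanger gene, rising from 2.45 to 7.98 and Klf1 from 1.32 to 4.66. Alas2, with 15.5% of its exon length in other genes, stood at 3.77 against 4.25. Neutrophil markers had 10 of 14 members higher and a median of 0.51, with S100a8 at 9038 against 5070, Mpo at 10.7 against 5.56 and Cxcr2 at 94.5 against 108 CPM.

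Across the 13865 genes compared in CD74+ cells, 928 were at least 2-fold higher with periostin and 728 at least 2-fold lower, 6.69% and 5.25% of them. Sampling of reads alone gave 0.2 in each direction, in simulated pairs that held counting noise only. Noise from library preparation or culture was not simulated, so the 0.2 does not cover it. Which direction held more genes depended on the processing. The counts higher and lower were 436 and 546 at a minimum of 5 CPM, 688 and 795 with the length trend removed, and 1112 and 1401 with genes left out of the table included, the last 2 chosen after seeing the data. The genes left out add many with 0 reads with periostin. Whether those values are real or arose at a technical step, such as the authors' counting, is not known. The list percentiles were 98.7 for MHC class II, 98.0 for MHC class I, 0.16 for angiogenic factors, 1.44 for integrins, 99.5 for immediate-early genes, 99.8 for genes of mitochondrial DNA, 99.9 for neutrophil markers and 99.98 for erythroid markers. Oxidative phosphorylation lay at 99.99 and ribosomal proteins at 100. The change with periostin fell with gene length across these genes (Spearman -0.32 across genes), from a median log2 change of 0.45 in the decile of shortest genes to -0.28 in the decile of longest genes. With random lists matched on length as well, chosen after seeing the data, oxidative phosphorylation lay at a percentile of 61.7, mitochondrial DNA genes at 79.3, MHC class II at 84.3, class I and neutrophil markers at 94.98, immediate-early genes at 97.0 and integrins at 18.9, all inside. With its 5 expression bins alone, integrins came inside at 3.08 and the other 9 lists lay outside, as all 10 did with GC content matched. With length matched, inflammatory cytokines (0.79) and matrix remodelling enzymes (1.93) lay outside on the lower side, and angiogenic, ribosomal and erythroid genes remained outside. Without matching on expression the MHC class I, immediate-early and integrin lists came inside, a pseudocount of 5 brought MHC class II (97.4) and integrins (2.70) inside and left 126 and 209 genes, and a minimum of 5 CPM brought MHC class I inside at 96.5.

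**Figure D2:**
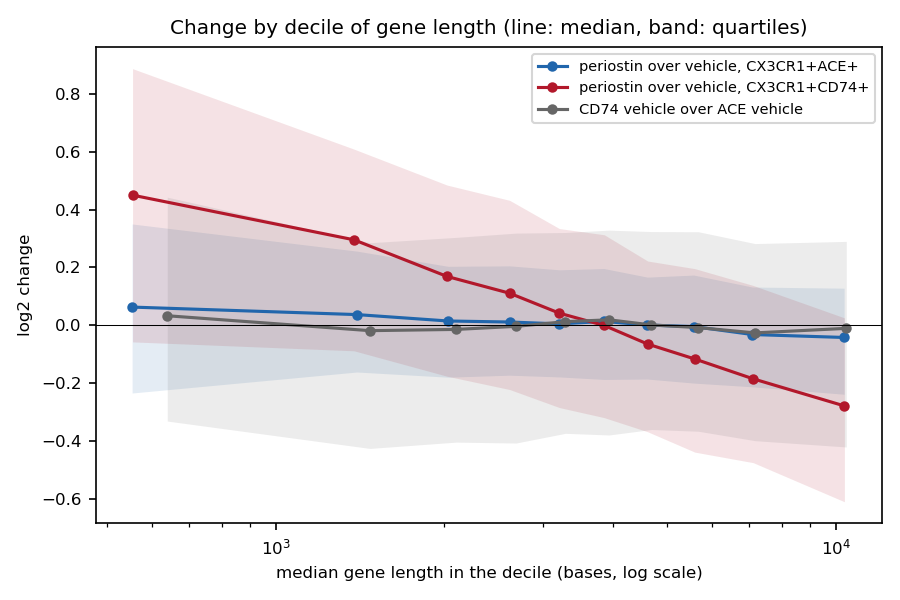
Log2 change (vertical axis) by decile of gene length in bases (horizontal axis, log scale) for periostin over vehicle in both subsets and for CD74+ over ACE+ vehicle, 1 library per group. Points are medians and bands quartiles over genes; the CD74+ medians run from 0.45 to -0.28, the ACE+ medians from 0.06 to -0.04.

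The remaining lists lay inside the random range in both subsets. Median log2 changes in ACE+ and CD74+ cells were 0.06 and 0.28 for chemokines, -0.12 and 0.04 for interferon-stimulated genes, and 0.01 and 0.03 for alternative activation and tissue repair. Neurotrophic and axon guidance factors had -0.08 and -0.19, osteogenic and growth factors 0.05 and 0.14, TGF-beta target genes 0.07 and 0.10, and the cell cycle 0.06 and -0.08. For hypoxia and glycolysis the medians were -0.04 and -0.01, for cholesterol synthesis and efflux 0.09 and -0.13, for lysosome and phagocytosis 0.07 and 0.04, and for the unfolded protein and heat shock response 0.00 and 0.06. Periosteal stromal and osteoblast markers had 0.09 and -0.18, endothelial markers 0.10 and -0.18, dendritic cell markers 0.15 and 0.18, and monocyte markers 0.07 and 0.22. Muscle markers had -0.06 and 0.14, and nerve and Schwann cell markers -0.06 and -0.06. Mast cell and basophil markers had 0.08 in ACE+ cells, and 4 members gave only a value of 0.03 in CD74+ cells. The 4 sort markers gave 0.03 and 0.11. Of lists outside the range in 1 subset, the other subset had medians of 0.00 for MHC class I, 0.02 for angiogenic factors, 0.02 for integrins, 0.06 for oxidative phosphorylation, 0.05 for immediate-early genes, 0.07 for mitochondrial DNA and 0.10 for erythroid genes in ACE+ cells. In CD74+ cells these were 0.08 for macrophage identity, -0.23 for inflammatory cytokines, 0.09 for NF-kB feedback, -0.07 for osteoclast genes, -0.11 for matrix remodelling and -0.21 for lymphocyte markers. The median and mean differed in sign for integrins (mean -0.08) and alternative activation (mean -0.02) in ACE+ cells, and for osteogenic factors (mean -0.07), osteoclast genes (mean 0.10) and nerve markers (mean 0.12) in CD74+ cells.

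The periostin responses of the subsets were set against each other over 13129 genes to ask whether they were shared. Across genes they were weakly correlated. Prg2 rose in both subsets, from 1.79 to 12.9 CPM in CD74+ cells, and so did Loxl2, from 11.2 to 24.0. Kcna3 and Lmbrd2 fell in both subsets, from 31.5 to 14.8 and from 10.3 to 3.88 CPM in ACE+ cells. Genes with opposite responses included Col10a1, which rose from 25.7 to 64.6 in ACE+ cells and fell in CD74+ cells, and Prg4, which rose in ACE+ cells and fell from 99.6 to 23.1 in CD74+ cells. As a list, chondrocyte markers lay inside the random range in CD74+ cells, with 8 of 19 higher, 11 lower, a median log2 change of -0.14 and a percentile of 19.6. They summed to 1553 and 1165 CPM there with vehicle and periostin. Whether cartilage genes such as Col10a1 and Prg4 changed in macrophages or in cartilage cells of the libraries was not tested. Itih3 and Gpr153 fell in ACE+ cells and rose in CD74+ cells, from 6.16 to 30.3 and from 12.0 to 46.7 CPM.

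Log2 changes differed most, in favour of ACE+ cells, for Col10a1 (5.90), Prg4 (4.31), Ctse (3.59), the T-cell coreceptor gene Cd4 (3.18) and Mfap5 (3.11). In favour of CD74+ cells they differed most for Dkk1 (-3.97), Itih3 (-3.92), Gpr153 (-3.55), the ubiquitin ligase gene Hecw2 (-3.36) and Marco (-3.23), each given as ACE+ minus CD74+. The response was at least 4-fold larger in ACE+ cells for 87 genes and at least 4-fold smaller for 106. Which side held more depended on the processing, with 57 and 27 at a minimum of 5 CPM and 107 and 92 with the length trend removed, the last chosen after seeing the data. Pseudocounts of 0.1 and 5 gave 277 and 338 and 4 and 7. The correlation of the log2 changes across genes was 0.09 by Spearman and 0.06 by Pearson, and 53.6% of genes changed in the same direction. At the 2-fold rule 21 genes rose in both subsets and 8 fell in both, where independent lists give 6.48 and 6.50. Another 12 rose in ACE+ and fell in CD74+ cells, and 28 did the reverse, where independent lists give 6.93 and 6.08. All 4 counts depended on the processing, recomputed after seeing the data. In the order given they were 112, 47, 39 and 95 at pseudocount 0.1, where independent lists give 24.5, 22.2, 24.1 and 22.6. They were 1, 0, 2 and 2 at pseudocount 5, where independent lists give 0.160, 0.111, 0.287 and 0.0624. At a minimum of 5 CPM they were 8, 4, 7 and 7, where independent lists give 1.11, 1.54, 2.26 and 0.756. With the length trend removed 17 genes fell in both, where independent lists give 7.47. The pairs share no library, genes are not independent replicates, and no difference between the responses was tested. A fit in edgeR with subset as a block, added after seeing the data and with 1 residual degree of freedom, found 8 genes higher and 6 lower with periostin at a Benjamini-Hochberg adjusted 0.05. At an unadjusted p under 0.05 it found 405 and 471, together 6.67% of genes. Prg2 and Loxl2 were among the 8, with log2 changes of 2.85 and 2.10 and adjusted p of 0.000455 and 0.00407. Col2a1, which rose in ACE+ cells but stood at 676 against 730 CPM in CD74+ cells, was also among the 8. Kcna3 and Lmbrd2, which fell in both subsets, were among the 6. So was Col10a1, which went opposite ways in the subsets. A gene could therefore pass this fit without a like response in both subsets, and a call alone does not show a shared effect. With the deposited size factors in place of TMM, 2 genes were higher and 0 lower.

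**Figure D3:**
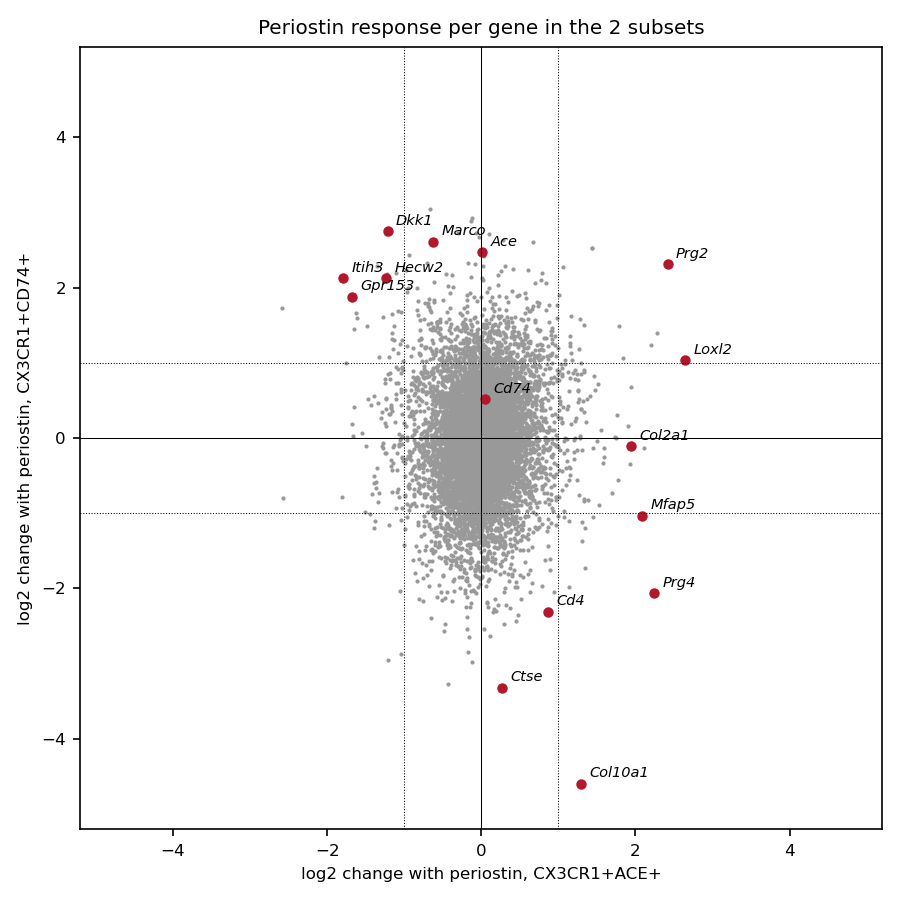
Log2 change with periostin of each gene in CX3CR1+ACE+ (horizontal axis) and CX3CR1+CD74+ (vertical axis) macrophages, 1 library per group, for 13129 genes. Dotted lines mark the 2-fold rule and red points are named genes; Col10a1 and Prg4 lie at the lower right, Dkk1, Itih3 and Gpr153 at the upper left, and the Spearman correlation is 0.09.

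Vehicle libraries of both subsets were compared to describe how the cells differed without periostin; their levels come from separate deposited tables scaled together. CD74+ cells had more of several cartilage and macrophage genes and far less of B-cell and red-cell genes than ACE+ cells. Prg4 was 17.1-fold (13.8 to 21.3) and aggrecan, Acan (ENSMUSG00000030607, GRCm38 chromosome 7, 79053483 to 79115099), 7.34-fold (6.43 to 8.40) higher in CD74+ cells. The macrophage elastase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) was 7.35-fold (6.68 to 8.10) and neuropeptide Y, Npy, 17.2-fold (13.7 to 21.7) higher. Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197), which encodes a signalling chain of the B-cell receptor, was 18.9-fold (15.9 to 22.6) lower, at 8.25 against 156 CPM.

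Adra1a, an adrenergic receptor gene, was the other gene named as higher, at 11.5 against 0.565 CPM. Other B-cell genes were lower too, Cd79b at 8.73 against 163, Pou2af1 at 2.81 against 83.1 and Vpreb3 at 0.1196 against 25.6. Lysosome and phagocytosis genes were higher in CD74+ cells as a list (25 of 31 members, median log2 difference 0.62), as were macrophage identity (16 of 21, 0.50), interferon-stimulated (27 of 31, 0.51), inflammatory cytokine (10 of 16, 0.43) and cell cycle genes (24 of 35, 0.22). Chosen after the values were seen as examples, the scavenger receptor gene Cd36 stood at 814 against 168, Oas1a at 88.4 against 27.6 and Mki67 at 230 against 72.7 CPM, where the second value is that of ACE+ cells. Markers of several other cell types were lower in CD74+ cells. Lymphocyte markers had a median of -3.96 (5 of 6 lower), erythroid markers -2.32 (8 of 8), neutrophil markers -0.96 (14 of 14), dendritic cell markers -0.66 (8 of 12), monocyte markers -0.57 (9 of 14), endothelial markers -0.67 (11 of 14), and periosteal stromal and osteoblast markers -0.63 (16 of 23). Muscle markers (-0.43, percentile 23.2) and nerve and Schwann cell markers (-0.20, percentile 26.5) lay inside the random range. Osteoclast genes (11 of 18, -0.25), integrins (18 of 25, -0.23) and ribosomal proteins (48 of 53, -0.21) were lower too. Of the chondrocyte markers, 18 of 19 were higher in CD74+ cells, 16 of them at least 2-fold, with a median of 1.60. Xist, the non-coding RNA of the inactive X chromosome, had 117 and 82.1 CPM in CD74+ cells with vehicle and periostin and 0.251 and 0.687 in ACE+ cells, although the labels give male mice.

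Over 13393 genes, 488 were at least 2-fold higher and 1035 at least 2-fold lower in CD74+ than in ACE+ cells with vehicle, and 204 and 467 with a pseudocount of 5. Percentiles for these lists, a step added after seeing the data, were at least 98.86 for the higher lists and at most 1.84 for the lower ones. The inflammatory cytokine list had a mean of -0.09 beside its median of 0.43.

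**Figure D4:**
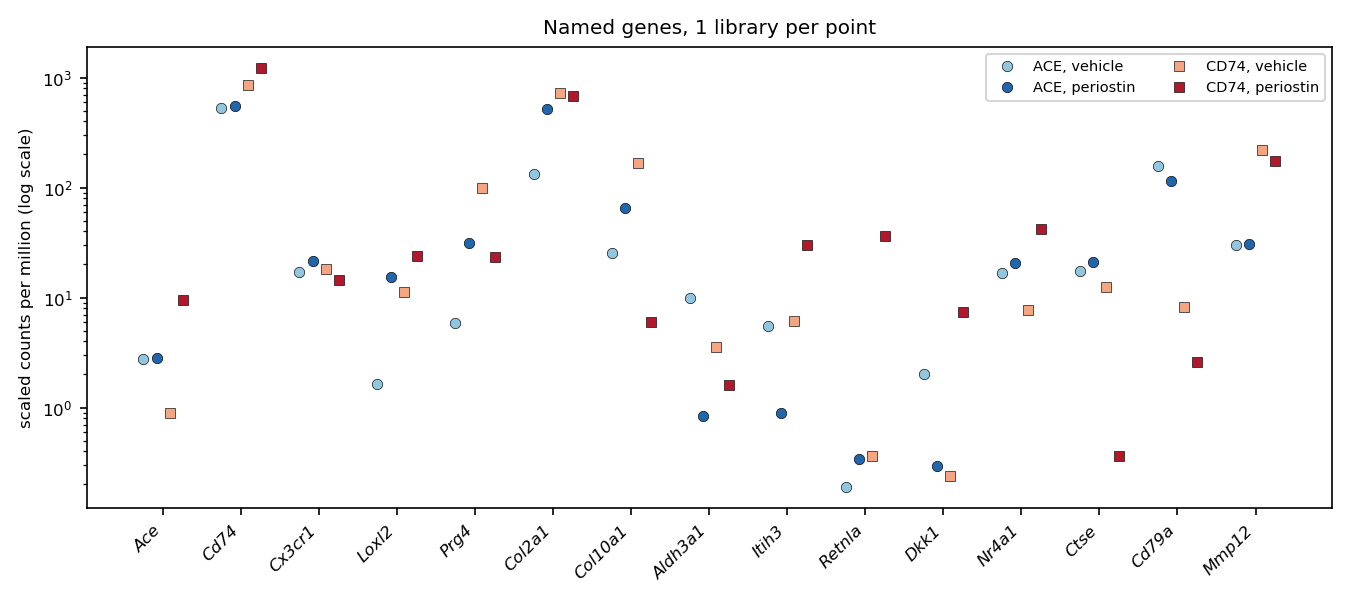
Scaled CPM (vertical axis, log scale) of named genes in the 4 libraries, 1 library per point, circles for CX3CR1+ACE+ and squares for CX3CR1+CD74+ macrophages. Retnla stands at 36.6 only in the CD74+ periostin library, and Col10a1 runs from 169 to 6.01 in CD74+ cells.

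Annotation terms for genes the authors took as higher with periostin were deposited for each subset. In the authors' deposited table for ACE+ cells the leading term was the proteinaceous extracellular matrix, with 75 genes, a fold enrichment of 3.35 and a Benjamini value of 8.27e-18, and the keyword Collagen had 21 genes and a value of 5.98e-05. In the authors' deposited table for CD74+ cells the keyword Mitochondrion led with 210 genes and 2.18e-16, ahead of Ribosomal protein with 65 genes and 1.79e-13, and oxidative phosphorylation had 34 genes and 0.00136. The authors' deposited tables held 637 and 548 terms, of which 71 and 43 had a Benjamini value under 0.05, and none of these was in both. The genes in the authors' deposited table for CD74+ cells had a median length of 2661 bases against 3384 for all listed genes, and those for ACE+ cells 3130 against 3229. In the authors' deposited table for ACE+ cells, 26.1% of the matched genes lay under 1 CPM in both libraries, against 14.3% of all listed genes.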

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

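The tests of cartilage and Xist reads were chosen only after those results were seen, whereas those of gene length, GC content and depth were chosen before their results were seen.

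Genes that changed at least 2-fold in opposite directions in the subsets stood out, with 1 library per group and no test of the difference. The log2 change in ACE+ minus that in CD74+ cells was 5.90 for Col10a1, 4.31 for Prg4, 3.11 for Mfap5, 2.24 for Aif1 and 2.13 for Adra1a, all higher in ACE+ and lower in CD74+ cells. It was -3.97 for Dkk1, -3.92 for Itih3, -3.55 for Gpr153, -3.36 for Hecw2, -3.10 for Crtam and -2.27 for Itga1, all in the reverse sense. Another 2 genes, absent from the deposited CD74+ table, had reads with periostin and 0 with vehicle when worked out from the deposited mean. Whether such a 0 is real or arose at a technical step, such as the authors' counting, is not known. Cdh22 had 62 reads or 5.56 CPM, at least 31.0-fold over the 3-read limit of the vehicle library, and Tm4sf5 had 59 reads or 5.29, at least 29.5-fold.

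Ribosomal protein and oxidative phosphorylation genes were higher with periostin in CD74+ cells, medians 0.39 and 0.28 on the log2 scale, in a comparison where the change fell with gene length, from 0.45 in the shortest to -0.28 in the longest decile. GC content is argued against by percentiles of 100 for both lists among random lists matched on GC content and expression. Gene length alone may account for the oxidative phosphorylation shift, whose percentile was 61.7 among lists matched on length and expression, whereas the ribosomal list lay at 98.5 with an excess of 0.11 over its random median. Thinning the vehicle library to 71.1% of its reads left medians of 0.385 for ribosomal and 0.275 for oxidative phosphorylation genes, but thinning keeps each gene's share of reads and could hardly have moved them, so it decides nothing about depth. Depth, whatever lies behind the length trend, reads shared with ribosomal pseudogenes and an effect of periostin all stay open, because each condition had 1 library.

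Cartilage genes were higher with periostin in ACE+ cells, with 19503 summed reads of 21 chondrocyte markers against 4963, a ratio of 3.07. The list was written after the data were seen and is not independent of them. Without the 6 markers named in any comparison, the other 15 had 3978 reads against 1676, a ratio of 1.86, and the lower bound of its counting interval, 1.75, argues against counting noise. Cartilage cells or their RNA are a candidate explanation, since 100% of the 15 markers past the filter were higher, including all 9 outside the genes named in any comparison, with a median of 0.88 on the log2 scale. The most abundant marker, Col2a1, had 134 and 520 CPM, and 2 of the 22 markers are also in the periosteal stromal list. Although the cells were sorted on CD45 and CX3CR1, the markers summed to 311 and 957 CPM in ACE+ cells with vehicle and periostin. In CD74+ cells they summed to 1553 and 1165, so their level also differed between the vehicle libraries. The test cannot separate cartilage cells from transcription in macrophages, so an effect of periostin on these genes stays open and untested. The same limit applies to the falls of Col10a1 and Prg4 in CD74+ cells.

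Xist stood at 117 and 82.1 CPM in the CD74+ libraries and at 0.251 and 0.687 in the ACE+ libraries, although the labels give male mice. With vehicle the 4 Y-linked genes had a median log2 difference of -0.59 between CD74+ and ACE+ cells, and their summed level had a ratio of 0.651 (0.616 to 0.688). Within subsets, where Xist differed far less, the Y-linked genes had a median log2 change with periostin of -0.28 in ACE+ and -0.85 in CD74+ cells. Their summed level had periostin over vehicle ratios of 0.833 (0.794 to 0.875) in ACE+ and 0.720 (0.668 to 0.776) in CD74+ cells. Because that last interval overlaps the difference between subsets, female cells among the CD74+ samples and Xist transcription in male cells cannot be told apart here.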

How the results depend on the processing

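Each group had 1 library, and no alternative adds replicates. A fit with subset as a block, added after seeing the data, gave 8 genes higher and 6 lower with periostin with TMM factors, 2 and 0 with the deposited size factors (321 and 447 at an unadjusted p under 0.05), and 12 and 9 without a filter; the cause was not tested. Counts of genes depended on the pseudocount by construction, since a larger one shrinks every log2 change, most of all for weakly expressed genes. At pseudocount 0.1 the counts higher and lower became 644 and 574 in ACE+ cells (217 and 191 as reported), 1463 higher in CD74+ cells (928), and 802 higher between vehicle libraries (488), while 277 and 338 genes (87 and 106) had a 4-fold larger or smaller response in ACE+ cells. At pseudocount 5 they fell to 19 and 9 in ACE+ cells, 126 and 209 in CD74+ cells, 204 and 467 between vehicle libraries, and 4 and 7 for the difference. A minimum of 5 CPM left fewer genes to count, 74 and 65 in ACE+ cells, 436 higher in CD74+ cells, and 57 and 27 for the difference. The 1.5-fold threshold gave by construction more, 907 and 858 in ACE+, 2307 and 1955 in CD74+ cells, and 1596 and 2271 between vehicle libraries. Including genes left out of the tables, an alternative chosen after seeing the data, gave 1112 genes higher (928) and 1401 lower in CD74+ cells (728). It adds genes with 0 reads with periostin, and whether those 0 values are real or arose at a technical step, such as the authors' counting, is not known. Without a filter no 2-fold count changed by 1.5 times or more, since the pseudocount keeps genes under 1 CPM from being called. Both rescalings and removal of the length trend, the last chosen after seeing the data, moved these counts by less than 1.5 times. Removal of the length trend nevertheless gave 107 and 92 genes with a 4-fold larger or smaller response in ACE+ cells (87 and 106). Every gene called at 2-fold with periostin also passed the binomial test, chosen after seeing the data, so that test says nothing about how firm the counts are. Lower genes outnumbered higher ones in CD74+ cells at pseudocount 5, a minimum of 5 CPM, removal of the length trend and inclusion of unlisted genes. Overlaps of the 2-fold calls, recomputed after seeing the data, were 21 higher in both subsets, 8 lower in both, 12 higher in ACE+ and lower in CD74+ cells, and 28 the reverse. In that order they became 112, 47, 39 and 95 at pseudocount 0.1, 1, 0, 2 and 2 at pseudocount 5, and 8, 4, 7 and 7 at a minimum of 5 CPM. These settings change how many genes are called, so the overlaps move with them. Removal of the length trend gave 17 lower in both, and the cause was not tested. The Spearman correlation between responses stayed between 0.05 and 0.10 in all its alternatives. Lists that stood apart numbered 5 in ACE+ cells (9) with unmatched random lists, and the cause was not tested. In CD74+ cells (10) they numbered 5 with lists matched on length and 9 with its 5 expression bins alone, both chosen after seeing the data. Most of that loss therefore came with the matching on length, not with the coarser expression bins. Lymphocyte markers in ACE+ cells reversed, to a median log2 change of -0.13 at a minimum of 5 CPM, where the weakly expressed T-cell and NK-cell genes drop out. Matching on GC content and matching on expression in 5 bins, both chosen after seeing the data, gave 10 and 9 lists apart in ACE+ cells and 11 and 9 in CD74+ cells. Lists inside the range came outside it under some alternatives. In ACE+ cells these were interferon-stimulated genes on the lower side, at a percentile of 2.45 with both rescalings, cholesterol genes on the upper side (97.6 to 97.95) with both pseudocounts and both rescalings, and, with a minimum of 5 CPM, erythroid markers at 98.5 and lysosome genes at the limit of the range. Matching on GC content brought out mitochondrial DNA genes (99.8), oxidative phosphorylation (97.53) and, on the lower side, hypoxia and glycolysis (2.10). In CD74+ cells chemokines did so with pseudocount 0.1 (98.0), both rescalings (97.6) and matching on GC content (97.96), besides the inflammatory cytokine, matrix remodelling and neurotrophic lists given elsewhere. In all 10 alternatives the calls for MHC class II and NF-kB feedback in ACE+ cells and for angiogenic, erythroid and ribosomal genes in CD74+ cells held. Of 126 log2 changes of named genes, 47 moved beyond their counting interval at pseudocount 5, 2 at pseudocount 0.1, 2 with TMM and 1 with the median ratio, and none changed sign. Depth limits the folds of genes with few vehicle reads, such as Marco with 1 read.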

Other observations

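Single genes outside the naming rule were picked after their values were seen, and stand for no list. In CD74+ cells Sema3c, an axon guidance factor, fell from 4.90 to 1.61 CPM, Wnt10b, a Wnt ligand, from 8.07 to 0.628, and Inhba, which encodes the activin A subunit, from 7.12 to 1.17. The collagenase Mmp13 fell from 26.8 to 4.84 and the mineralization inhibitor Mgp from 64.3 to 18.1. Whether these falls took place in macrophages or in other cells of the libraries was not tested. Osteogenic and growth factors as a list had 13 of 24 members higher and a median log2 change of 0.14 in CD74+ cells. Of its members Wnt10b and Inhba fell and Wnt5a and Tnfsf11 rose at least 2-fold, while Igf1 stood at 54.3 against 35.2 and Bmp7 at 4.75 against 2.33. In ACE+ cells Wnt10b had 4.20 and 5.40 and Mmp13 23.3 and 24.8 CPM with vehicle and periostin. The complement gene C1qa and a clearance receptor went the other way in CD74+ cells, where C1qa rose from 14.6 to 36.9 and Timd4, a receptor for apoptotic cells, from 0.598 to 6.46, while Mertk, another such receptor, fell from 14.5 to 3.77. These genes belong to lists that lay inside the expression-matched random range, although matrix remodelling enzymes, which include Mmp13, lay outside it on the lower side when length was matched too (1.93), and neurotrophic factors did so at a minimum of 5 CPM (1.25).

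Genes absent from the deposited CD74+ table were mostly ones with reads in the vehicle library alone, 1822 of them against 290 with reads in the periostin library alone and 700 with none in either. Of these 1822 genes, 29 reached 5 CPM with vehicle and 0 reads with periostin. Among them were the BMP antagonist gene Grem1 with 10.8, the Wnt antagonist genes Wif1 with 6.52 and Sfrp5 with 5.38, the chemokine gene Ccl7 with 6.70 and the integrin gene Itga2 with 5.14 CPM with vehicle. Zbed6 had 405 reads and Sept1 249 reads with vehicle and 0 with periostin, where ACE+ cells had 30.5 and 38.3 CPM with vehicle and 27.9 and 38.7 with periostin. Whether a 0 in the CD74+ periostin library is real or arose at a technical step, such as the authors' counting, is not known. These values are therefore not read as decreases. Of genes absent from the ACE+ table, 123 had reads with vehicle alone, 131 with periostin alone and 68 in neither, and none reached 5 CPM.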
